A study of Mus musculus with 6 samples.

How the data were processed

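Gene expression was taken from the table that the authors deposited for the series, which holds 55222 genes in 6 liver libraries: normal, CCl4 with AAV-Ctrl, and CCl4 with AAV-shPhpt1, with 2 libraries in each group. The header of the table names no unit. The deposited values behave as FPKM: the columns sum to different totals, and a value times the gene's transcript length is a whole multiple of 1 step per library. The submitters' processing notes name the aligner Bowtie 0.12.2 and the builds mm8 and mm9. Whether Bowtie aligned the reads behind this table, and the counter, the annotation and the build used for it, are not given in the sources used here. Per the labels, libraries were made from total RNA with a TruSeq kit. Groups were taken from the sample titles, and all 6 libraries and all sample columns were used.

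Of the 55222 entries, 54532 carried an Ensembl identifier and 690 were loci without a name. Symbols came from the deposited table, and coordinates and transcript lengths from the GENCODE M21 annotation of GRCm38, where 54495 identifiers matched. Multiplying FPKM by the mean length of a gene's annotated transcripts and by the library's own step gave whole reads, within a tolerance of 0.05 reads, for 96.3% to 96.6% of values. These recovered reads were used for the depth per library, for counting intervals and for 2 alternative tests. The implied totals were 21488841 and 23929101 reads in normal livers, 22118741 and 24067312 in AAV-Ctrl, and 23608353 and 24188029 in AAV-shPhpt1. Intervals for ratios of reads are exact conditional binomial intervals at 95%, shares have Wilson intervals, and both cover counting error only. Replicates differed by a chi-squared per gene of 46.74, 48.33 and 89.9 in normal, AAV-Ctrl and AAV-shPhpt1, so no library repeats another.

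The design allowed for counts or normalized values, and the rule for normalized values applied. Genes with a mean of at least 1 FPKM in at least 1 group were kept, 13517 in all, and log2(FPKM + 1) was fitted with limma 3.58.1 (limma-trend) in R 4.3.3. One fit over the 6 libraries gave 3 comparisons: AAV-Ctrl against normal, AAV-shPhpt1 against AAV-Ctrl, and AAV-shPhpt1 against normal. The spread was shared by all groups, with 3 residual degrees of freedom and a prior of 3.21. Tests were two-sided, and genes passed at a Benjamini-Hochberg adjusted p under 0.05 with no fold limit. Adjusted p values of single genes are from limma. Fold values in the text are ratios of group means of FPKM, and values after ± are SDs of 2 libraries or, where stated, SEs of the fitted log2 difference. The labels do not say that the libraries come from separate animals, so the p values measure the spread between samples. With groups of 2, no permutation of the samples could reach 0.05, and other splits of the samples were not counted.

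The gene lists, 42 in number with 623 different genes, were written from textbook knowledge before the data were examined, as were the comparisons, the tests and most of the alternative settings. They cover collagens, matrix glycoproteins, matrix remodelling, stellate cells, TGF-beta signalling, macrophages, Kupffer cells, neutrophils, T and NK cells, B cells, sinusoidal endothelium, cholangiocytes, pericentral and periportal hepatocytes, secreted hepatocyte proteins and transcription factors, drug metabolism, NRF2 targets, NADPH oxidase, cell cycle, p53 targets, acute phase, chemokines, interferon-stimulated genes, fatty acid oxidation, lipogenesis, cholesterol synthesis, bile acids, glycolysis, ER stress, coagulation and complement, sex-biased liver genes, fetal liver, histidine phosphorylation, clock, immediate early and heat shock genes, mitochondrially encoded transcripts, and transcripts of red blood cells, exocrine pancreas, skeletal muscle, adipose tissue and mesothelium. The lists of exocrine pancreas and adipose tissue had 1 measured gene each and were not tested, which left 40 with at least 5. Each was tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 40 lists. Camera compares a list with all other genes, so a list can rank below them with a median near 0. Camera with an estimated correlation kept 0 of the calls in each comparison. In the simulation of the hairpin comparison described below, that form called a list of independent genes shifted by -0.75 in 0 of 20 runs. Its power for larger shifts, for correlated genes and for the other comparisons was not simulated. Its adjusted p values are printed beside the calls, and calls that it did not keep rest on the preset correlation. Fry, which asks whether a list's genes move on balance in 1 direction or change in either, was run beside camera. Where no test is named, a list called or not called refers to camera at the preset correlation.

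The genes named in the text follow a rule fixed in advance: Phpt1; in each comparison the 8 largest rises and 8 largest falls among genes past the threshold with non-overlapping groups and a mean of at least 5 FPKM in the higher group, filled up by the smallest p where fewer passed; up to 4 members per list with the smallest p; and 15 key genes of fibrosis, injury and liver. Predicted genes, small RNA genes and receptor segments were left out of the largest changes.

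The share of genes changed in AAV-Ctrl against normal that differed with opposite sign in AAV-shPhpt1 against AAV-Ctrl was set beside 100 simulated data sets in which the hairpin group had the AAV-Ctrl means. The correlation of both comparisons with normal livers was set beside 100 in which it had the normal means. The test was also tested on simulated data of the hairpin comparison, with 200 changed genes among 13517 in 20 runs. It recovered 31.1% of 2-fold and 88.1% of 4-fold changes with a false share of calls of 6.2% and a mean bias of -0.006. All simulated groups had the same spread per gene, so the wider spread of the AAV-shPhpt1 group was not imitated. A list of 15 genes shifted by -0.75 was called in 20 runs with the preset correlation and in 0 with an estimated one, and 0 of 780 unshifted lists were called. Simulated genes varied independently and lists were random, whereas estimated correlations were 0.508 for collagens and 0.581 for interferon-stimulated genes. The 0 of 780 therefore does not measure false calls among the real lists.

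Alternative settings fixed in advance were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, quantile normalization, median centring, limma without trend, the replicate number as a block, only the 4 libraries compared, a limit of 1 on the log2 change, and leaving out each library. Limma-voom on the recovered reads, scaled by library totals or by median-of-ratios factors, and array quality weights were added after the data had been seen. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Raw reads were not used here. The result of 1 single gene is not reported here.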

Results

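RNA from mouse liver was sequenced in 6 libraries that form 3 groups of 2: normal livers, livers of mice given carbon tetrachloride (CCl4) and a control adeno-associated virus (AAV-Ctrl), and livers of mice given CCl4 and a virus carrying a short hairpin RNA against Phpt1 (AAV-shPhpt1). CCl4 is a solvent that liver cytochromes convert into a toxic radical, and repeated injections injure the liver and scar it. Phpt1 encodes a phosphatase that removes phosphate from histidine. Per the labels, 12.5 ml/kg CCl4 was injected 2 times per week, the virus was given into a vein after 1 week, and livers were taken 48 h after the last CCl4 dose. The CCl4 was diluted in oil, and whether the stated volume includes the oil, and for how long CCl4 was given, are not given in the sources used here. The labels state 5 mice per group, without saying which animals gave the libraries. The header of the deposited table names no unit. Its values behave as FPKM and were read as such, and the reads they imply range from 21488841 to 24188029 per library. The normal libraries had neither CCl4 nor virus, so the effects of both cannot be separated in a comparison with them.

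The normal livers lay apart from all livers given CCl4 on the first principal component, which held 64.1% of the variance. Their scores were -59.06 and -57.11, against 32.75 and 45.58 in AAV-Ctrl. The AAV-shPhpt1 libraries differed from each other, with 40.1 in replicate 1 and -2.26 in replicate 2. The SD between replicates over all genes, on the log2 scale, was 0.306 in normal livers, 0.28 in AAV-Ctrl and 0.439 in AAV-shPhpt1. Genes more than 2-fold apart between replicates made up 3.6%, 2.7% and 9.5% of those tested.

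**Figure D1:**
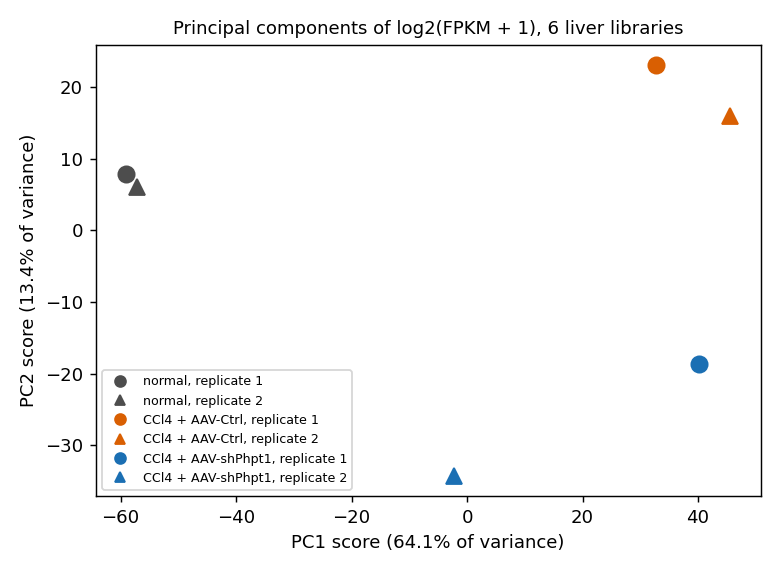
Scores of the 6 libraries on the first 2 principal components of log2(FPKM + 1), which hold 64.1% and 13.4% of the variance; each point is 1 library, coloured by group. AAV-shPhpt1 replicate 2 (first score -2.26) sits between the normal livers and the other livers given CCl4.

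Phpt1 itself was examined first, as the gene the hairpin targets. In the GRCm38 annotation Phpt1 (ENSMUSG00000036504) lies on chromosome 2 from 25573430 to 25575224, on the minus strand. Its deposited values were close to 0 in all 6 libraries, between 0.0521 and 0.2594 FPKM. These values correspond to 4 and 4 reads in normal livers, 4 and 1 in AAV-Ctrl, and 4 and 5 in AAV-shPhpt1. The ratio of AAV-shPhpt1 to AAV-Ctrl, from 9 against 5 reads and relative to library totals, was 1.74, with an exact 95% interval for counting error of 0.52 to 6.61. For AAV-Ctrl against normal it was 0.61 (0.16 to 2.13). A knockdown was not detectable at this depth, and Phpt1 was below the filter of the gene test. With no filter its log2 difference was 0.12, with an adjusted p of 0.805. All 375 coding bases of Phpt1 lie within exons of the neighbouring gene Mamdc4 (ENSMUSG00000026941) on the same strand. Of its 1074 exonic bases 418 (38.9%) are shared with that gene and the others are not. With 1 to 5 reads per library, the values do not show whether the target was lowered.

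In livers given CCl4 and the control virus, genes of scar matrix, of the cells that deposit it and of macrophages were several-fold higher than in normal livers. The collagen gene Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) averaged 66.9 ± 8.01 FPKM (SD, n = 2) against 2.27 ± 0.474, a 29.5-fold rise. Acta2 (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590), the smooth muscle actin of activated stellate cells, rose 7.06-fold to 15.9 ± 1.89 FPKM (n = 2). Adgre1, which encodes the macrophage surface protein F4/80, rose 11.8-fold. Of 17 measured genes of the hepatocytes around the central vein 7 fell. Among them were Cyp2e1 (ENSMUSG00000025479, chromosome 7, 140763739 to 140774987), the cytochrome that activates CCl4, which was 12.1-fold lower, and Glul, glutamine synthetase, 13.3-fold lower. For each gene named below as risen or fallen, both libraries of 1 group lay beyond both libraries of the other.

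The matrix genes moved together. Of 15 measured collagen genes, 13 rose over all genes tested and 14 when adjusted over the list alone, with a median log2 change of 2.18. The set ranked above the other genes with adjusted p = 3.93e-05 (camera, preset correlation), against adjusted p = 0.517 with an estimated correlation. Col1a2 rose 22.4-fold, Col3a1 17.0-fold and Col4a1, a basement membrane collagen, 9.94-fold. Matrix glycoproteins, proteoglycans and crosslinking enzymes gave 12 risen genes of 20 (18 adjusted over the list alone, median 1.85, adjusted p = 2.78e-05, and adjusted p = 0.517 with an estimated correlation). Sparc, a collagen-binding glycoprotein, went from 17.8 ± 5.23 to 148.7 ± 6.82 FPKM (n = 2). Lox, which crosslinks collagen, reached 2.51 ± 0.0661 FPKM from 0.00577 ± 0.00815 (n = 2). Matrix remodelling genes rose in 13 of 15 cases (15 adjusted over the list alone, median 1.76, adjusted p = 1.85e-05, and adjusted p = 0.497 with an estimated correlation). They include Timp1, an inhibitor of matrix metalloproteinases, which rose 76.7-fold, and the metalloproteinase Mmp14, which rose 3.51-fold.

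Stellate cell and myofibroblast markers rose in 8 of 16 cases (9 adjusted over the list alone, median 1.5, adjusted p = 0.00782, and adjusted p = 0.517 with an estimated correlation). The intermediate filament gene Vim rose 10.3-fold, the tropomyosin Tpm1 5.22-fold and Pdgfrb, a growth factor receptor of stellate cells, 7.50-fold. Des, desmin, rose 4.03-fold. Of 16 genes of TGF-beta signalling, 8 rose (12 adjusted over the list alone, median 0.88, adjusted p = 0.00719, and adjusted p = 0.517 with an estimated correlation). The target gene Ctgf rose 10.3-fold and Tgfb1 itself 4.64-fold. Tgfb1 and Des no longer passed after median centring, with adjusted p = 0.0903 and 0.0704.

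Macrophage genes showed the highest list median, at 2.88 on the log2 scale. Of 15 monocyte and macrophage markers, 14 rose (15 adjusted over the list alone, adjusted p = 6.92e-06, and adjusted p = 0.517 with an estimated correlation). Lgals3, galectin-3, rose 28.8-fold and the lysozyme gene Lyz2 10.7-fold. Gpnmb, a glycoprotein of lipid-laden macrophages, went from 0.0958 ± 0.0621 to 49.3 ± 1.19 FPKM, and the macrophage metalloproteinase gene Mmp12 from 0.0672 ± 0.0271 to 39.2 ± 12.5 FPKM (n = 2). Of 8 Kupffer cell markers only the scavenger receptor gene Marco passed, at 191.1 ± 38.3 against 2.83 ± 0.757 FPKM (n = 2), and the set was not called (adjusted p = 0.268). Chemokines and inflammatory mediators gave 13 risen and 1 fallen gene of 16 (14 and 1 adjusted over the list alone, adjusted p = 0.00285, and adjusted p = 0.573 with an estimated correlation). Ccl2, which attracts monocytes, rose 18.7-fold and Cxcl9, an interferon-induced chemokine, 8.11-fold. Interferon-stimulated genes rose in 12 of 20 cases (17 adjusted over the list alone, median 1.16, adjusted p = 2.61e-04, and adjusted p = 0.557 with an estimated correlation), among them Oas1a with a 5.18-fold rise. Ccl2 and Adgre1 no longer passed after median centring, with adjusted p = 0.0740 and 0.0539. Markers of neutrophils (adjusted p = 0.81), T and NK cells (0.379), B and plasma cells (0.81) and sinusoidal endothelium (0.062) were not called as sets, with 1, 0, 0 and 4 members risen.

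Among hepatocyte genes, part of those of the pericentral zone fell. Of 17 pericentral genes 7 fell, also when adjusted over the list alone, and none rose, with a median of -0.98 (adjusted p = 1.51e-11, and adjusted p = 0.423 with an estimated correlation). Slc1a2, a glutamate transporter of the cells beside the central vein, went from 93.7 ± 10.9 to 0.124 ± 0.0638 FPKM (n = 2). Of 18 periportal genes 2 rose and 2 fell (2 and 5 adjusted over the list alone, median -0.56, adjusted p = 1.07e-05, and adjusted p = 0.423 with an estimated correlation). The gluconeogenic enzyme gene Pck1 was among the fallen, 4.43-fold lower. Male-biased liver genes had the lowest list median, -2.13, with 3 of 10 fallen (4 adjusted over the list alone, adjusted p = 1.46e-08, and adjusted p = 0.423 with an estimated correlation). Susd4 and Selenbp2 of that list were 58.7-fold and 6.61-fold lower. The major urinary protein genes Mup7 and Mup11 were 34.9-fold and 444-fold lower, and Mup19 was listed at 0 in both AAV-Ctrl libraries. Mup and Cyp2c genes have near-identical copies, so how their reads were shared among copies is uncertain. General hepatocyte genes went both ways. Alb, albumin, averaged 74140 against 75630 FPKM (adjusted p = 0.98). The list of secreted proteins and transcription factors had a median of -0.13 and 2 risen members of 17, Apob (1.70-fold) and Trf (1.74-fold). Apoa1 was 2.13-fold lower without passing (adjusted p = 0.058), and fry called changes in either direction in this list (adjusted p = 0.00273). It still ranked below the other genes (adjusted p = 2.21e-04, and adjusted p = 0.423 with an estimated correlation), since the median over all genes was 0.353, and quantile normalization ended that call (adjusted p = 0.482).

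Several metabolic lists ranked below the other genes as well, while cholesterol synthesis and glycolysis ranked above them. Drug metabolism gave 2 risen and 3 fallen genes of 20 (2 and 6 adjusted over the list alone, adjusted p = 7.19e-07, and adjusted p = 0.423 with an estimated correlation). Bile acid synthesis and transport gave 1 risen and 4 fallen of 19 (1 and 5 adjusted over the list alone, adjusted p = 5.6e-07, and adjusted p = 0.43 with an estimated correlation), including the hydroxylase gene Cyp7b1, 7.26-fold lower. For fatty acid oxidation and PPAR-alpha targets 6 of 23 genes fell and 1 rose, the same numbers adjusted over the list alone (adjusted p = 2.23e-06, and adjusted p = 0.423 with an estimated correlation). The fatty acid binding protein gene Fabp1 was 3.38-fold lower. Coagulation and complement genes fell in 3 of 24 cases (2 adjusted over the list alone, adjusted p = 1.42e-07, and adjusted p = 0.423 with an estimated correlation), and mitochondrially encoded transcripts in 1 of 13 (1 adjusted over the list alone, adjusted p = 4.42e-07, and adjusted p = 0.471 with an estimated correlation). Quantile normalization ended the calls of drug metabolism (adjusted p = 0.116) and of periportal genes (adjusted p = 0.0872).

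Lists of stress responses, cell cycle, cholesterol synthesis and glycolysis ranked above the other genes, each with members that did not pass. Of 16 targets of NRF2, the regulator of antioxidant genes, 12 rose (13 adjusted over the list alone, median 2.18, adjusted p = 2.82e-04, and adjusted p = 0.423 with an estimated correlation). Srxn1, sulfiredoxin, rose 7.85-fold, and the glutathione transferase genes Gstm1 and Gsta1, which have close copies, 5.85-fold and 224-fold. Among p53 targets 8 of 16 rose (9 adjusted over the list alone, adjusted p = 0.00719, and adjusted p = 0.517 with an estimated correlation), led by the cell cycle inhibitor Cdkn1a with 96.5-fold. Cell cycle genes rose in 6 of 24 cases (7 adjusted over the list alone, adjusted p = 0.0235, and adjusted p = 0.72 with an estimated correlation), with Ccnd1, cyclin D1, 6.94-fold and the replication gene Mcm6 9.21-fold higher. Mki67 averaged 3.48 against 0.372 FPKM without passing (adjusted p = 0.14). The cell cycle call ended without AAV-Ctrl replicate 1 (adjusted p = 0.171) and without normal replicate 2 (0.119). ER stress genes rose in 10 of 14 cases (11 adjusted over the list alone, adjusted p = 0.0235, and adjusted p = 0.648 with an estimated correlation), among them Ddit3 with 6.29-fold. That call ended without AAV-Ctrl replicate 2 (adjusted p = 0.0782) and without AAV-shPhpt1 replicate 1 (0.0673) or 2 (0.0686). These belong to neither group compared but enter the shared spread and the expression filter, and the cause was not tested. Cholesterol synthesis gave 9 risen genes of 19 (11 adjusted over the list alone, adjusted p = 0.0192, and adjusted p = 0.517 with an estimated correlation) with Hmgcs1 3.54-fold higher, and glycolysis 5 of 14 (9 adjusted over the list alone, adjusted p = 0.0112, and adjusted p = 0.517 with an estimated correlation) with Pkm 12.5-fold higher. Without AAV-Ctrl replicate 1 the adjusted p was 0.158 for cholesterol synthesis and 0.0532 for glycolysis, and median centring ended the call of cholesterol synthesis (adjusted p = 0.0571).

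In total 2464 genes rose and 308 fell of 13517 tested (limma, adjusted p under 0.05), with 5608 at an unadjusted p under 0.05. The largest rises by rule were Sprr1a, Gsta1, Ly6d, Marco, Gpnmb, Mmp12, Lcn2 and Cdkn1a, and the largest falls Mup17, Mup11, Slc1a2, Mup7, Cyp2c37, Mup1, Mup19 and Cyp2c40. Sprr1a was listed at 0 in both normal libraries and reached 90.6 ± 76.4 FPKM (n = 2), and the acute phase gene Lcn2 rose 30.9-fold. Of 20 acute phase genes 7 rose (9 adjusted over the list alone), and that set was not called (adjusted p = 0.0659). The excess of risen genes depended on the scaling, since the median over all genes was 0.353 on the log2 scale: median centring gave 566 risen and 729 fallen genes and quantile normalization 632 and 460. Of 40 lists 14 ranked above and 10 below the other genes, 0 with an estimated correlation, and fry called 14 in 1 direction and 31 in either. The gene count needed all 4 libraries compared, with 13 and 7 genes without normal replicate 1 or 2 and 18 and 6 without AAV-Ctrl replicate 1 or 2.

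**Figure D2:**
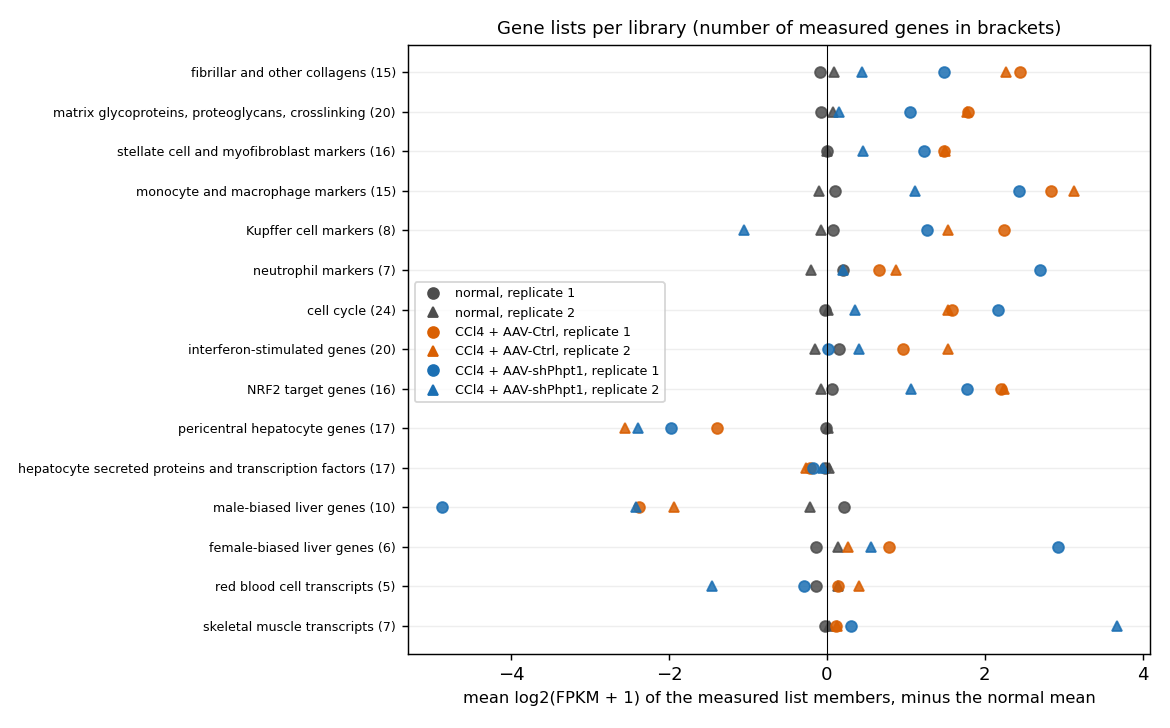
Mean log2(FPKM + 1) of the measured members of 15 gene lists in each library, minus the mean of the normal livers; each point is 1 library (circles replicate 1, triangles replicate 2). Collagens stand at 2.45 and 2.27 in AAV-Ctrl, and at 1.48 and 0.45 in AAV-shPhpt1.

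Livers given the hairpin against Phpt1 were compared with those given the control virus under the same CCl4 treatment, the comparison the series is about. Values of matrix, macrophage and interferon-stimulated genes were lower with the hairpin, and no single gene passed the test. Col1a1 averaged 17.6 ± 15 FPKM against 66.9 ± 8.01 (SD, n = 2), with 28.2 in replicate 1 and 6.94 in replicate 2 (adjusted p = 0.49). Acta2 averaged 2.96 ± 0.832 against 15.9 ± 1.89 FPKM, at 3.54 and 2.37 in the single AAV-shPhpt1 libraries (adjusted p = 0.43). The gene lists below are therefore described by their set tests and by counts adjusted over the list alone.

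Matrix genes were lower as sets by camera at the preset correlation. Of 15 collagens, 14 were lower when adjusted over the list alone and 0 over all genes tested, with a median of -1.37 (camera, adjusted p = 2.03e-10, and adjusted p = 0.486 with an estimated correlation). Col1a2 had a log2 difference of -2.19 (SE 0.50), Col3a1 -2.36 (SE 0.59), Col4a1 -1.63 (SE 0.33) and Col15a1 -1.55 (SE 0.31). Of 20 matrix glycoproteins, proteoglycans and crosslinking enzymes 13 were lower adjusted over the list alone (median -1.21, adjusted p = 4.02e-12, and adjusted p = 0.486 with an estimated correlation). Examples are Lox at -1.39 (SE 0.28) and Tnc, tenascin C, at -1.65 (SE 0.36). Fry in 1 direction gave adjusted p = 0.311 for collagens and 0.311 for the glycoprotein list. Matrix remodelling genes had a median of -0.94 and 1 gene lower adjusted over the list alone (adjusted p = 5.5e-05, and adjusted p = 0.486 with an estimated correlation). Timp1 had -1.52 (SE 0.51). Stellate cell and myofibroblast markers had a median of -0.41, with 3 of 16 lower adjusted over the list alone (adjusted p = 0.00368, and adjusted p = 0.486 with an estimated correlation), Acta2 and Vim among them. This call ended without AAV-shPhpt1 replicate 2 (adjusted p = 0.217). Pdgfrb had -0.97 (SE 0.31) and Des -0.21 (SE 0.28). TGF-beta signalling was not called (median -0.25, adjusted p = 0.149), and Tgfb1 stood at 18.1 and 4.65 FPKM in the AAV-shPhpt1 replicates against 17.5 ± 1.57. The mean of the collagen list above normal was 2.45 and 2.27 in AAV-Ctrl, 1.48 in AAV-shPhpt1 replicate 1 and 0.45 in replicate 2.

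Interferon-stimulated genes stood closer to the normal level in both libraries with the hairpin. The list mean above normal was 0.96 and 1.53 in AAV-Ctrl, against 0.01 and 0.41 in AAV-shPhpt1. Of 20 genes 11 were lower adjusted over the list alone and 0 over all genes, with a median of -0.98 (adjusted p = 8.1e-14, and adjusted p = 0.486 with an estimated correlation). Oasl1 had a log2 difference of -1.36 (SE 0.21), Oas1a -1.01 (SE 0.18) and Ifit3 -1.19 (SE 0.24). Camera at the preset correlation kept this call in all 6 fits that left out 1 library, but these fits share most of their libraries. The estimated correlation of this list was 0.581, far above the preset 0.01. Fry in 1 direction gave it an adjusted p of 0.311. Ifi27l2a and the guanylate-binding protein gene Gbp10, interferon-induced genes outside the list, had -2.28 (SE 0.35) and -2.13 (SE 0.30). Both were named for being among the smallest p values of this same comparison, so they add no separate support. Neither passed the gene test.

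Macrophage markers were lower mainly in replicate 2. Monocyte and macrophage markers had a median of -1.34 and 0 genes lower adjusted over the list alone (adjusted p = 8.68e-06, and adjusted p = 0.486 with an estimated correlation). Adgre1 stood at 18.9 and 2.47 FPKM against 52.8 ± 8.32, and Fcgr1 at a log2 difference of -2.20 (SE 0.48). Kupffer cell markers had a median of -1.73 (adjusted p = 1.01e-04, and adjusted p = 0.486 with an estimated correlation), with Marco at 116.0 and 20.2 FPKM against 191.1 ± 38.3 and Cd5l at -2.33 (SE 0.92). The Kupffer list mean relative to normal was 1.27 in replicate 1 and -1.05 in replicate 2. NADPH oxidase subunits had a median of -1.03 (adjusted p = 0.00385, and adjusted p = 0.486 with an estimated correlation). Chemokines had a median of -0.74 (adjusted p = 0.0201, and adjusted p = 0.605 with an estimated correlation), a call that ended without AAV-Ctrl replicate 2 (adjusted p = 0.677) and without AAV-shPhpt1 replicate 2 (0.353). Ccl2 averaged 4.70 ± 1.81 against 9.02 ± 7.80 FPKM. Sinusoidal endothelial markers had a median of -0.73 (adjusted p = 0.00106, and adjusted p = 0.605 with an estimated correlation), a call that ended without AAV-Ctrl replicate 1 (0.0832) and without AAV-shPhpt1 replicate 2 (0.242). Neutrophil markers were higher as a set, with a median of 0.83 (adjusted p = 0.041, and adjusted p = 0.605 with an estimated correlation). Their list mean was 2.7 in AAV-shPhpt1 replicate 1 and 0.21 in replicate 2. That call held in 1 of 5 fits that left out 1 library, with adjusted p of 0.48 and 0.107 without AAV-Ctrl replicate 1 or 2 and 0.0656 and 0.0637 without normal replicate 1 or 2. Quantile normalization (0.245) and median centring (0.16) ended it too. Without AAV-shPhpt1 replicate 1 the neutrophil list had too few measured genes to test. Some of its members thus passed the expression filter only through that library. B and plasma cell markers (median 0.38, adjusted p = 0.0299, and adjusted p = 0.605 with an estimated correlation) lost their call without AAV-Ctrl replicate 2 (0.44) and reversed without AAV-shPhpt1 replicate 1 (0.539). Their call also ended after quantile normalization (0.0747) and median centring (0.0999).

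Lists of hepatocyte and metabolic genes were called in both directions. Periportal genes had a median of 0.44 (adjusted p = 2.83e-06, and adjusted p = 0.486 with an estimated correlation), with Sds, serine dehydratase, at 0.77 (SE 0.19) and Pck1 at 0.62 (SE 0.18). Pericentral genes were not called (median -0.54, adjusted p = 0.434). Cyp2e1 averaged 242.6 ± 35.4 against 509.4 ± 438 FPKM and Glul 31.6 ± 17.9 against 69.3 ± 14.1. NRF2 targets were lower, with a median of -0.76 and 5 of 16 genes lower adjusted over the list alone (adjusted p = 1.69e-04, and adjusted p = 0.486 with an estimated correlation), among them Srxn1 at -0.77 (SE 0.20) and Gstp1 at -1.33 (SE 0.30). Lipogenesis (median 0.39, adjusted p = 0.00368), mitochondrially encoded transcripts (0.21, 0.00199), secreted hepatocyte proteins (0.15, 0.0171) and fatty acid oxidation (0.06, 0.0268) ranked above the other genes (the median over all genes was -0.066), and cholesterol synthesis (-0.26, 0.00491) and glycolysis (-0.27, 0.0171) below them. Of the fatty acid oxidation genes 12 were positive and 11 negative. In that order they had adjusted p = 0.605, 0.545, 0.486, 0.486, 0.486 and 0.486 with an estimated correlation. Without AAV-Ctrl replicate 2 the first 4 had adjusted p of 0.856, 0.474, 0.107 and 0.654, and without AAV-Ctrl replicate 1 cholesterol synthesis and glycolysis had 0.206 and 0.0975. Without AAV-shPhpt1 replicate 1 lipogenesis had 0.0844 and cholesterol synthesis 0.539, and without replicate 2 the remaining 4 had 0.487, 0.552, 0.906 and 0.242. Median centring ended the calls of secreted proteins (0.0638) and fatty acid oxidation (0.0579).

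Genes that differ between the sexes in liver were called in opposite directions. Male-biased genes were lower, with a median of -1.59 (adjusted p = 0.00368, and adjusted p = 0.545 with an estimated correlation). Female-biased genes were higher, with a median of 1.09 (adjusted p = 0.00179, and adjusted p = 0.486 with an estimated correlation). Both calls rested on AAV-shPhpt1 replicate 1, where the male-biased list mean was -4.87 relative to normal, against -2.42 in replicate 2, and the female-biased mean 2.93 against 0.56. Without replicate 1 the male-biased set reversed. The female-biased list, with 6 of 15 members measured, then had too few measured genes. The expression filter thus admitted some of its members only through replicate 1, so the change tested helped to decide which members were tested. Without AAV-Ctrl replicate 2 the female-biased call ended (0.0844). Elovl3, a male-biased elongase gene, was listed at 0 and 7.25 FPKM in the AAV-shPhpt1 replicates against 28.0 ± 1.73, and the female-biased cytochrome gene Cyp2b9 at 34.0 and 0.331 against 0.0453 ± 0.0299.

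Transcripts of other tissues also differed with the hairpin group. Skeletal muscle transcripts had a median of 1.70 (adjusted p = 2.93e-05, and adjusted p = 0.486 with an estimated correlation), and they stood at 3.67 above normal in AAV-shPhpt1 replicate 2 against 0.31 in replicate 1. Without replicate 2 this list had too few measured genes to test, so some members passed the expression filter only through that library. Acta1, skeletal muscle actin, was at 41.3 FPKM in replicate 2 and 0.123 in replicate 1. Red blood cell transcripts had a median of -1.15 with 1 of 5 lower adjusted over the list alone, Alas2 at -1.60 (SE 0.39), and an adjusted p of 0.00477 (adjusted p = 0.486 with an estimated correlation). Without AAV-shPhpt1 replicate 2 that adjusted p was 0.487, and the list mean was -1.45 in replicate 2 against -0.29 in replicate 1. Mesothelial transcripts, from the liver's surface lining, had a median of -0.83 with 3 of 5 lower adjusted over the list alone (adjusted p = 3.37e-04, and adjusted p = 0.486 with an estimated correlation), including Msln at -1.17 (SE 0.27). Cell cycle genes were not called (median -0.22, adjusted p = 0.697), and Mki67 stood at 7.69 FPKM in replicate 1 and 0.466 in replicate 2 against 3.48 ± 0.0293 in AAV-Ctrl.

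The gene test gave 0 genes over 13517 (limma, smallest adjusted p = 0.307), with 1146 at an unadjusted p under 0.05, of which 211 were higher and 935 lower, against 676 by chance. Limma-voom on recovered reads gave 0 genes with either scaling. Of 40 lists 9 ranked above and 16 below the other genes, 0 with an estimated correlation, and fry called 0 in 1 direction and 1 in either. The genes with the smallest p by rule, none of which passed, were Hsd17b6, Klhl24, Tcp11l2, Igfbp2, Pdcd4, mt-Rnr1, Mme and Ulk1 on the higher side and Cyp1a2, Blvrb, Nat8f5, Cela1, Gbp10, Cebpb, Oasl1 and Ifi27l2a on the lower. Hsd17b6, a steroid dehydrogenase gene, averaged 454.8 ± 9.46 FPKM against 103.5 ± 25.8, and Nat8f5 0.719 ± 0.348 against 10.6 ± 0.381 (n = 2). The count was 377 (39 higher, 338 lower) without AAV-shPhpt1 replicate 1, which leaves replicate 2 alone, and 5 (3 and 2) without AAV-shPhpt1 replicate 2. In a simulation of this comparison with 200 changed genes limma recovered 31.1% of 2-fold and 88.1% of 4-fold differences. It gave all groups the same spread per gene, while the SD between replicates was 0.439 in AAV-shPhpt1 against 0.28 in AAV-Ctrl. The simulation can therefore overstate the recovery here. Under its spread and its mix of 2-fold and 4-fold differences, most single 2-fold differences were missed. Data with 2-fold differences alone were not simulated, so the count of 0 genes does not show how many such differences exist.

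Genes that changed after CCl4 were then followed into the hairpin comparison. Of the 2772 genes changed in AAV-Ctrl against normal, 2380 (85.9%) had a difference of opposite sign in AAV-shPhpt1 against AAV-Ctrl, and 0 were called there in the opposite direction by limma. Both comparisons share the AAV-Ctrl libraries, which gives opposite signs by chance. Simulated groups without any hairpin effect gave a mean of 59.8% (57.9% to 61.6% over 100 draws). Each simulated gene varied independently, with the same spread in all groups given CCl4. Real genes vary together within a library, and the SD between replicates was 0.439 in AAV-shPhpt1 against 0.28 in AAV-Ctrl. The simulated range can therefore be too narrow, and it does not show that the observed share lies beyond chance. Across genes, which are not independent replicates, the correlation of both differences was -0.481 against a simulated -0.189, and their covariance -0.156 against -0.043. With separate single AAV-Ctrl libraries for each comparison the correlation was -0.421 or -0.229. For AAV-shPhpt1 replicate 1 alone the opposite share was 74% with a correlation of -0.165, and for replicate 2 alone 88.9% with -0.594. Values without a hairpin effect were not simulated for a single library, so neither can be set against the simulated values above. The shares with separate AAV-Ctrl libraries were 91.5% and 73.2%, with an SD of 10.5 percentage points between the shares of the single AAV-shPhpt1 libraries, and no share was simulated for this form. Refits without AAV-shPhpt1 replicate 1 or 2 gave 90.6% of 3737 and 66% of 3739 genes, and no share without a hairpin effect was simulated for these. Refits without a normal or AAV-Ctrl library left 6 to 18 changed genes, with shares from 57.1% (7 genes) to 88.9% (18 genes). The matrix, macrophage and interferon genes named above, such as Col1a1, Adgre1 and Oas1a, are among the genes of opposite sign.

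**Figure D3:**
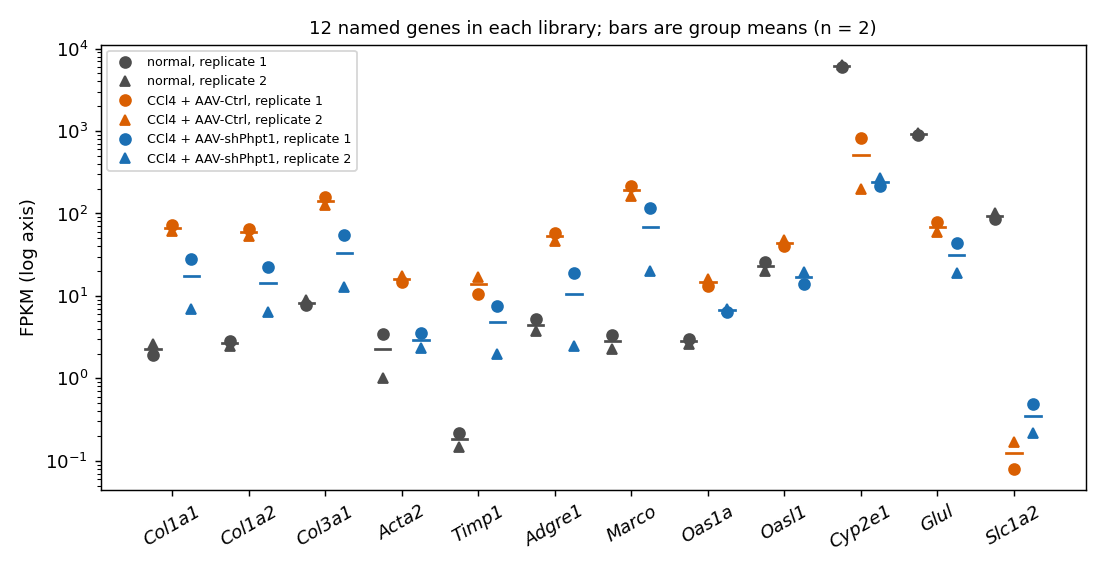
FPKM on a log axis of 12 named genes in each library, with bars at the group means (n = 2); circles are replicate 1 and triangles replicate 2. Col1a1 is at 28.2 and 6.94 FPKM in AAV-shPhpt1 against a mean of 66.9 in AAV-Ctrl, while Slc1a2 stays below 1 FPKM in all livers given CCl4.

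The livers with the hairpin were last compared with normal livers, to see how far they remained from them. Of 17 measured pericentral genes 6 were called lower than in normal livers, and several injury genes stayed high. Cyp2e1 was 25.4-fold lower than in normal livers, at 242.6 ± 35.4 against 6170 ± 243 FPKM (SD, n = 2), and Glul 29.2-fold lower. Lgals3 was 19.4-fold and Nupr1, a stress-induced nuclear protein gene, 102-fold higher. The scar and macrophage genes Col1a1 (7.75-fold, adjusted p = 0.072), Col3a1 (4.03-fold, 0.14), Acta2 (1.31-fold, 0.51) and Adgre1 (2.39-fold, 0.57) did not pass.

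Pericentral genes fell in 6 of 17 cases (12 adjusted over the list alone, median -1.47, adjusted p = 9.18e-17, and adjusted p = 0.48 with an estimated correlation), with Slc1a2 at 0.354 ± 0.195 FPKM against 93.7 ± 10.9 and Cyp1a2 2.78-fold lower. Male-biased genes fell in 3 of 10 cases (10 adjusted over the list alone, median -3.98, adjusted p = 6.88e-14, and adjusted p = 0.48 with an estimated correlation). Susd4 and Selenbp2 were 84.9-fold and 18.9-fold lower. Bile acid genes gave 1 risen and 1 fallen gene of 19, the fallen being Cyp7b1 at 24.9-fold lower (1 and 9 adjusted over the list alone, median -0.81, adjusted p = 8.31e-07, and adjusted p = 0.48 with an estimated correlation). Collagens had a median of 0.94 with 0 of 15 risen over all genes and 3 adjusted over the list alone, Col1a1 and Col1a2 among them, and were not called (adjusted p = 0.0822). Matrix glycoproteins (median 0.58, adjusted p = 0.31) and stellate cell markers (0.71, adjusted p = 0.175) were not called either. Vim and Tpm1 of the latter rose 4.34-fold and 5.02-fold, and Des at 3.51-fold did not pass (adjusted p = 0.055). Vim no longer passed after quantile normalization (adjusted p = 0.0773) or median centring (0.0572). Matrix remodelling genes rose in 5 of 15 cases (7 adjusted over the list alone, adjusted p = 0.00608, and adjusted p = 0.674 with an estimated correlation), with Mmp14 3.01-fold and Plaur 14.9-fold higher. That call ended without normal replicate 2 (adjusted p = 0.0621), and Mmp14 no longer passed after quantile normalization (0.0504) or median centring (0.0516).

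Monocyte and macrophage markers rose in 4 of 15 cases (9 adjusted over the list alone, median 1.49, adjusted p = 0.00272, and adjusted p = 0.737 with an estimated correlation). Interferon-stimulated genes gave 1 risen gene of 20, Oas1a at 2.39-fold, also adjusted over the list alone, with a median of 0.22 (adjusted p = 0.441). Oas1a no longer passed after median centring (adjusted p = 0.111). NRF2 targets gave 5 risen and 1 fallen gene of 16 (11 and 1 adjusted over the list alone, adjusted p = 0.00349, and adjusted p = 0.48 with an estimated correlation), Srxn1 rising 4.54-fold. Without normal replicate 2 the adjusted p of this list was 0.0524. Among p53 targets 3 of 16 rose (11 adjusted over the list alone, adjusted p = 0.0021, and adjusted p = 0.674 with an estimated correlation), with Cdkn1a 62.5-fold higher. ER stress genes rose in 3 of 14 cases (11 adjusted over the list alone, adjusted p = 0.00311, and adjusted p = 0.674 with an estimated correlation). Kupffer cell markers were not called (median -0.38, mean 0.11, adjusted p = 0.106).

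Altogether 441 genes rose and 145 fell against normal (limma, 4282 at an unadjusted p under 0.05). The largest rises by rule were Sprr1a, Nupr1, Ly6d, Gsta1, Mmp12, Mt1, Anxa2 and Lgals3, and the largest falls Mup7, Mup17, Mup11, Slc1a2, Mup1, Mup19, Glul and Mup12. Of these Mmp12 no longer passed after quantile normalization (adjusted p = 0.0685) or median centring (0.0588). Of the genes called against normal in both virus groups, 529 moved the same way and 1 the opposite way. Both comparisons share the normal libraries, which correlates them by chance. The correlation of both differences across genes was 0.82, against a mean of 0.188 (0.158 to 0.223 over 100 draws) for simulated hairpin livers at the normal level. The real livers had been given CCl4 and virus too, so a value above the simulated one was likely beforehand. The simulated genes also varied independently, and the gap does not measure how far these livers remained from normal. Of 40 lists 8 ranked above and 11 below the other genes, 0 with an estimated correlation, and fry called 0 in 1 direction and 23 in either. This split depended on the scaling: 20 lists ranked above and 9 below after median centring, and 17 and 4 after quantile normalization. Median centring gave 128 risen and 185 fallen genes and quantile normalization 114 and 122. The gene count was 9 without normal replicate 1, 9 without normal replicate 2, 33 and 132 without AAV-Ctrl replicate 1 or 2, 75 without AAV-shPhpt1 replicate 1 and 2289 without AAV-shPhpt1 replicate 2.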

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

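Limma-voom on recovered reads and array quality weights were chosen after the data had been seen; the other settings were fixed before. Settings for counts (edgeR, DESeq2 and their scalings) did not apply to FPKM. The cause was not tested for any change below.

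For AAV-Ctrl against normal the count of 2772 stayed within 1.5 times with pseudocounts of 0.1 and 5, a filter at 5 FPKM, no trend, the replicate block (2162), 4 libraries, voom with library totals and array weights. It was 96 with no filter, which tests more genes near 0, 1092 after quantile normalization, 1295 after median centring, 1626 with a log2 limit of 1 and 1012 with voom and median-of-ratios factors. Of the 1295, 874 were among the 2772. Leaving out 1 library gave 6 to 3739.

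For AAV-shPhpt1 against AAV-Ctrl the count was 0 under all of these settings, the replicate block included, and 0 to 377 without 1 library. For AAV-shPhpt1 against normal the 586 genes became 259 with a pseudocount of 5, 4 with no filter, 236 after quantile normalization, 313 after median centring, 233 without trend and 384 with the replicate block. They became 202 with 4 libraries, 179 and 123 with voom and library totals or median-of-ratios factors, 288 with array weights, and 9 to 2289 without 1 library. Where 1 library was left in a group, it was taken to vary like the others. Deviations of equal replicate numbers correlated at 0.073, 0.041 and 0.153 between groups. With 1 replicate difference per group these values cannot decide whether the numbers pair the samples, and no label states a pairing.

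The numbers of called lists (24, 25 and 19) stayed within 1.5 times under these settings, except 29 in the last comparison after median centring. Directions moved more than these totals. The lists above and below were 14 and 10, 9 and 16, and 8 and 11 in the main fit. Quantile normalization gave 19 and 6, 5 and 16, and 17 and 4, and kept 20, 21 and 12 of the main calls. The replicate block gave 24, 26 and 20, and an estimated correlation 0, 0 and 0. In AAV-shPhpt1 against AAV-Ctrl the adjusted p ranged from 7.47e-07 to 0.539 for B cell markers and from 7.95e-12 to 0.847 for male-biased genes without 1 library, each reversing without AAV-shPhpt1 replicate 1. Quantile normalization reversed periportal genes (0.64) and secreted hepatocyte proteins (0.853) in AAV-shPhpt1 against normal. The share of opposite signs, 85.9%, ranged from 57.1% (7 genes) to 90.6% (3737 genes) without 1 library.

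Single genes reversed in few settings, none while passing. Quantile normalization moved Acta2 to -0.01 and Alb to 0 (rounded) in AAV-shPhpt1 against normal. Without 1 library the log2 difference ranged from -0.08 to 0.02 for Alb in AAV-Ctrl against normal. In AAV-shPhpt1 against AAV-Ctrl it ranged from -1.71 to 0.04 for Tgfb1, -0.57 to 0.15 for Des, -1.76 to 0.27 for Cyp2e1, -1.61 to 0.95 for Mki67 and -1.48 to 0.3 for Ccl2. In AAV-shPhpt1 against normal it ranged from -0.2 to 0.96 for Acta2 and -0.64 to 1.88 for Adgre1. Phpt1 moved from 0.12 to 0.59 with a pseudocount of 0.1 and was 0.01 to 0.23 without 1 library, and its 1 to 5 reads per library limit what can be seen. Of 64 named genes in AAV-Ctrl against normal, refits without 1 library ended a call in 220 of 384 cases and reversed 1.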

Other observations

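All tests of explanations below were chosen after the results had been seen. Clock genes differed after CCl4. In AAV-Ctrl against normal 4 of 14 rose and 3 fell (4 and 6 adjusted over the list alone), with a median of -0.84 (camera, adjusted p = 2.82e-04, and adjusted p = 0.456 with an estimated correlation), and median centring ended the set call (adjusted p = 0.114). Dbp, an output gene of the clock, was 20.6-fold lower, and Arntl, a core activator, went from 0.984 ± 0.941 to 10.1 ± 0.227 FPKM (SD, n = 2), without passing after quantile normalization (adjusted p = 0.0509). The hour at which livers were taken is not given in the sources used here. The histidine phosphorylation list was not called by camera (adjusted p = 0.514), while fry called it in 1 direction (adjusted p = 0.0484). Of its 6 measured genes 3 rose (4 risen and 1 fallen adjusted over the list alone). Gnb1, which carries a phosphohistidine that Phpt1 is known to remove, rose 1.90-fold, and the kinase gene Nme1 2.24-fold, neither passing after median centring (adjusted p = 0.088 and 0.11). Lhpp, which encodes another histidine phosphatase, was 4.21-fold lower in AAV-Ctrl without passing (adjusted p = 0.053), though it passed after median centring (0.0435), and 8.84-fold lower in AAV-shPhpt1 against normal (adjusted p = 0.044).

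The imprinted fetal gene H19 was listed at 0 in both AAV-Ctrl libraries and stood at 3.61 and 3.45 FPKM in AAV-shPhpt1 (adjusted p = 0.43, and 3.8e-04 adjusted over the list alone). Against normal it rose from 0.0355 ± 0.0027 to 3.53 ± 0.108 FPKM (n = 2, adjusted p = 0.018), and the fetal list was not called in AAV-Ctrl against normal (adjusted p = 0.255). In AAV-shPhpt1 against AAV-Ctrl camera did not call the fetal list of 5 measured genes (adjusted p = 0.65). Fry called changes in either direction there (adjusted p = 9.1e-05). Only H19 passed adjusted over the list alone, and it met the expression filter only through AAV-shPhpt1. The other 4 genes were negative, and the list median was -0.13. Whether the fry call depends on H19 was not tested. In AAV-Ctrl against normal, cholangiocyte and ductular markers were not called by camera (adjusted p = 0.153), while fry called them in 1 direction (adjusted p = 0.0416). Sox9 and Spp1 rose 5.08-fold and 4.10-fold in AAV-Ctrl and 7.47-fold and 3.78-fold in AAV-shPhpt1 against normal. In AAV-Ctrl quantile normalization ended the calls of Sox9 (0.0714) and Spp1 (0.0502) and median centring that of Spp1 (0.0514). In AAV-shPhpt1 both ended that of Spp1 (0.0767). Both libraries of each group stood close, with list means of 0.72 and 1.05 in AAV-Ctrl and 0.84 and 1.01 in AAV-shPhpt1. Among immediate early and heat shock genes, a list that was not called (adjusted p = 0.67), Atf3 rose 53-fold in AAV-Ctrl and 35.5-fold in AAV-shPhpt1 against normal. Lipogenesis (adjusted p = 0.0826) and mesothelial transcripts (0.0505) were not called by camera in AAV-Ctrl against normal. Of 5 mesothelial genes 3 rose (5 adjusted over the list alone), and fry called that list in 1 direction (adjusted p = 0.0416). Red blood cell (0.405), skeletal muscle (0.153), female-biased (0.379) and NADPH oxidase (0.133) lists were not called by camera in that comparison either. Of 8 NADPH oxidase genes 6 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 2.21. The fallen gene was Nox4, 2.53-fold lower, and fry called changes in either direction in this list (adjusted p = 0.0419).

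Collagen and macrophage genes lay nearer to normal in AAV-shPhpt1 replicate 2 than in replicate 1. An admixture of normal liver RNA would have kept pericentral genes high, but the 7 that fell after CCl4 stood at a median of 4.34% of normal in replicate 2 (0.231% to 28.8%), which excludes it as the cause. Dilution by muscle RNA, whose transcripts are high in this library, would have lowered hepatocyte genes too, yet secreted hepatocyte proteins were 0.12 higher on the log2 scale than in replicate 1 while collagens differed by -1.03, which excludes it as the cause as well. A stronger knockdown in replicate 2 cannot be told apart, with 5 against 4 Phpt1 reads (exact binomial p = 1). A milder or later stage of injury, a different piece of liver and an effect of the hairpin that varies between animals remain open and were not tested.

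Male-biased genes were lowest and female-biased genes highest in AAV-shPhpt1 replicate 1. RNA of a female liver is excluded, since 4 Y-linked genes summed to 137% of the mean of the other 5 libraries. Dilution of hepatocyte RNA is excluded too, since secreted hepatocyte proteins were at -0.17 relative to normal, against -4.87 for the male-biased list. Growth hormone signalling, which sets these genes, and the hairpin itself stay open and were not tested.

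Phpt1 was near 0 in all libraries, normal livers included. One candidate explanation is that reads over exons shared with another gene were not assigned. It cannot be told apart from low expression. Of 24 genes like Phpt1, with all coding bases within exons of another gene but under 50% of exonic bases shared, 62.5% were below 1 FPKM (Wilson 95% interval 42.7% to 78.8%). Of 20894 genes that share no base 48.5% were (Fisher's exact p = 0.22), and 24 genes are too few to decide. Of all 264 genes with every coding base within such exons, most of which share more of their bases than the 38.9% of Phpt1, 93.2% were below 1 FPKM. Low expression of Phpt1 in liver was not tested separately.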
